A study of Mus musculus with 2 samples.

How the data were processed

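Gene expression was measured in hepatocellular carcinoma tissue from mice given DEN (diethylnitrosamine, a chemical liver carcinogen). One tumour sample came from a wild-type mouse and 1 from a mouse deficient in HLF (hepatic leukemia factor, a PAR bZIP transcription factor). Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cDNA was prepared with an Affymetrix whole-transcript labelling kit. The processed table held 35556 probe sets and 1 column for each of the 2 arrays.

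The deposited values are on a log2 scale. Per the submitters' processing notes they were made with RMA in Affymetrix Expression Console; no version is given there. The scale is not stated in the sources used here and was read from the values, which ran from 0.25 to 12.7 on the wild-type array and from 0.37 to 12.7 on the HLF-deficient array, and from RMA's usual output. RMA corrects background, equalises array distributions and summarises probes, so it compresses differences near background. The quantiles of the 2 columns were close but not identical: the medians were 3.73 and 3.61, and the 75th percentiles 5.47 and 5.61. Which arrays were normalized together is not given in the sources used here.

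Probe sets were named from the platform annotation. Exactly 1 gene was named for 21789 probe sets, several genes for 1621 and no gene for 12146; only the first kind entered the gene analysis. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6, where 21698 of the 21789 were found and no symbol changed. The probe sets covered 19938 genes. For the 999 genes with more than 1 probe set, the one with the highest mean over both arrays was used. The floor of expression was the 95th percentile of the 1245 probe sets of olfactory, vomeronasal and taste receptor genes, families that liver does not use, and lay at a log2 value of 2.96. The 14649 genes at or above the floor on at least 1 array were compared.

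There was 1 array per genotype, so no p-value, SD or confidence interval between tumours could be given, and the number of arrays limits the precision. The comparison used a fixed rule of size, a log2 difference (HLF-deficient minus wild-type) of at least 1 in either direction, which is 2-fold. As a guide to technical spread within an array pair, the differences of the 2 brightest probe sets of a gene were compared over 740 genes; the SD of a single probe set's difference, from the spread of these pairs, was 0.24. This does not cover differences between mice or between tumours. A gene below the floor on 1 array has only a bound there, and its fold is given as "at least", from the floor.

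There were 23 gene lists and 12 lists of cell type markers. For each list, the median log2 difference of its members at or above the floor was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when the percentile of its median among the random medians was under 2.5 or over 97.5; lists with fewer than 5 such members got no percentile. The percentile describes these 2 arrays and is not a test of genotype, because genes are not replicates. Of the 33 lists with a percentile, about 1.65 would lie outside by chance if genes were independent, and genes of 1 list are not independent.

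Genes named in the text are Hlf and Jun, the 12 with the largest difference in each direction, and up to 2 per direction from each list. Symbols of predicted or unnamed gene models, small RNAs and chemoreceptors were left out of the first 12; this concerned 19 of the genes beyond 2-fold. The order follows the measured difference, so the rank of a gene below the floor on 1 array, as Spink1, Sult3a1, Sult3a2, Cyp3a16 and Rsph4a were, is not established. Genes named outside this rule are said to have been chosen after their values were seen. The neighbours of a gene were taken from the order of genes in the same RefSeq table. The groups, lists, floor, rule of size, naming rule and alternatives were fixed before the data were examined. The alternatives were centring of each array, quantile normalization, removal of a loess trend with a span of 0.4, the mean of a gene's probe sets, other floors, rules of 1.5-fold and 4-fold, unmatched random lists and list means.

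The procedure was tested on simulated data made from the 14649 genes of the wild-type array with noise of SD 0.25. The 2-fold rule recovered 4.5% of 200 genes changed by 1.5-fold, 54.5% of 200 genes changed by 2-fold and 100% of those changed by 4-fold, and called 1 unchanged gene in each run. For the list runs, a trend of the difference with wild-type level was added to this noise. Of 200 unchanged lists of 17 genes, 7% lay outside the random range, and 100% of lists raised by 0.5 lay above it. The noise was chosen, is smaller than the SD of 0.38 of the measured differences, and holds no spread between mice or tumours. These runs therefore check how the rules work and give no rate of false calls for the 2 arrays. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.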

Results

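Tumour transcriptomes were compared between a wild-type and an HLF-deficient mouse after DEN treatment, to find genes expressed differently in hepatocellular carcinoma that arose without HLF. Each genotype was represented by 1 array, so every difference below is between 2 tumour samples, and whether it exceeds the spread between tumours cannot be known from these data. The 2 arrays correlated at r = 0.986 across 35556 probe sets, which are not independent replicates, and their medians were 3.73 and 3.61. Values are RMA expression on a log2 scale, and differences are HLF-deficient minus wild-type.

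Hlf, the targeted gene, was lower in the HLF-deficient tumour. Its log2 level was 5.13 in the wild-type and 3.79 in the HLF-deficient tumour, a difference of -1.34, or 2.54-fold. It ranked 22nd among the decreases of 14649 genes. The HLF-deficient value stayed above the floor of 2.96, and which exons the probe set covers in relation to the deleted part of the gene is not given in the sources used here. The direction goes with the genotype labels. Of the 20 expressed genes nearest to Hlf in the gene order of assembly GRCm38.p6, 0 differed by 2-fold, and their median difference was 0.03. The other PAR bZIP factors Dbp and Tef differed by 0.33 and 0.06 and the related repressor Nfil3 by 0.13; these 3 genes were named after their values were seen. The list of PAR bZIP and core clock genes had a median of 0.13, at percentile 46.9 of random lists. Within it, Per1 and Bhlhe40 had the largest positive values, 0.91 and 0.82, and Hlf was the only 1 of 17 members beyond 2-fold, joined by Per1 when each array was centred on its median (1.04).

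Of the 14649 genes, 219 were higher by at least 2-fold in the HLF-deficient tumour and 53 were lower. The other genes stayed closer, and 90.5% of all genes lay within 1.5-fold. Among the genes beyond 2-fold, 21 of the higher ones were below the floor in the wild-type tumour and 16 of the lower ones were below it in the HLF-deficient tumour. With values set to the floor, 205 higher and 42 lower genes remained beyond 2-fold. Genes above the floor had a median difference of 0.07 between the arrays, and centring the arrays on the median of all probe sets would add 0.12 to every difference. The difference also depended on level: in 6 groups of genes of rising mean expression the median was -0.20 in the dimmest, 0.24 in the second brightest and 0.16 in the brightest, a division chosen after the data were seen.

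**Figure D1:**
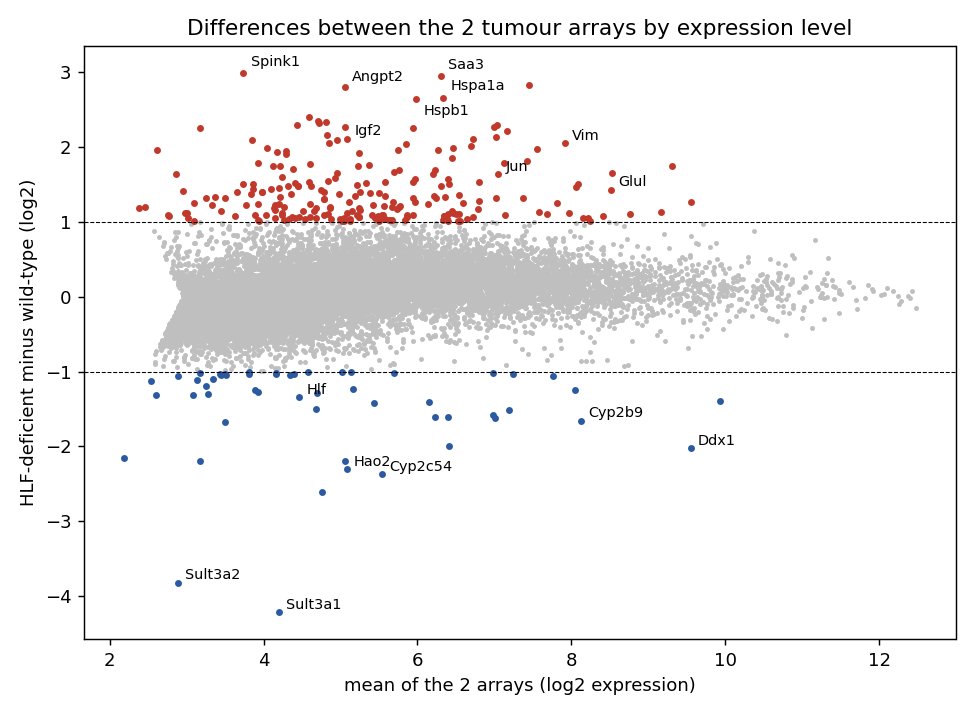
Log2 difference (HLF-deficient minus wild-type) against the mean log2 expression of the 2 arrays for 14649 genes, 1 point per gene, with dashed lines at 2-fold, the 219 higher genes in red and the 53 lower genes in blue. Hlf lies at -1.34 and Jun at 1.63, and the lowest points are Sult3a1 and Sult3a2, whose HLF-deficient values are below the floor.

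The genes with the largest increases included a protease inhibitor, acute phase, heat shock, vascular and inflammatory genes. Spink1, a secreted serine protease inhibitor, was below the floor in the wild-type tumour at 2.24 and reached 5.23, which is at least 4.82-fold higher. Saa3, an acute phase serum amyloid, was 7.67-fold higher. Angpt2, a secreted ligand of the endothelial receptor Tie2, was 6.98-fold higher. The inducible chaperones Hspa1a and Hspb1 were higher by 6.30-fold and 6.25-fold; both probe sets of Hspb1 gave the same direction, with differences of 2.64 and 2.74. Casp4, an inflammatory caspase, was 5.29-fold higher, the immediate early nuclear receptor Nr4a1 5.07-fold and Fos 4.82-fold. St14, a membrane serine protease, Cdh17, a cadherin of liver and intestine, Trp53i11 and the potassium channel subunit Kcne3 were higher by 5.03-fold, 4.97-fold, 4.91-fold and 4.90-fold.

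The largest decreases included genes of hepatic enzymes and transporters. Sult3a1, a sulfotransferase, had a log2 level of 6.30 in the wild-type tumour and lay below the floor at 2.09 in the HLF-deficient tumour, at least 10.2-fold lower. Its relative Sult3a2 was at least 3.57-fold lower. Slc22a26, of the organic anion transporter family, was 6.09-fold lower, Cyp2c54 5.18-fold, the peroxisomal oxidase Hao2 4.94-fold and Hamp2, a hepcidin-type gene, 4.59-fold. Cyp2b9 and Cyp2c50 were lower by 3.16-fold and 3.06-fold. Cyp3a16 had a level of 3.26 in the wild-type tumour and lay below the floor in the HLF-deficient tumour, which bounds the change only at 1.23-fold, and Rsph4a, a cilium component, was at least 2.60-fold lower. Ddx1, an RNA helicase gene, was 4.07-fold lower, with log2 levels of 10.56 and 8.54. Macrod2 was 3.97-fold lower in its brightest probe set, but 2 dimmer probe sets above the floor differed by -0.29 and -0.93. The mean was -1.07 over these 3 probe sets and -0.52 over all 6, of which 3 were not above the floor. Members of the Cyp2c, Cyp2b, Cyp3a, Sult3a, Saa and Hspa1 families are similar in sequence, and a probe set may read more than 1 of them.

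Among the lists fixed beforehand, 8 had medians above and 4 had medians below the range of random lists, while 21 were counted as inside. Among the latter the stellate cell and fibroblast list, lay on the boundary at percentile 2.5, its median marginally below the lower end of its range. With independent genes, chance would put about 1.65 of the 33 outside. The AP-1 and immediate early genes stood farthest above. Of its 18 members, 11 were higher by 2-fold and none was lower, with a median difference of 1.30 against a random range of -0.03 to 0.29. Jun, the AP-1 subunit c-Jun, was 3.10-fold higher, with log2 levels of 6.23 and 7.86. Fos differed by 2.27 and Atf3, a stress-induced bZIP factor, by 2.01, while Fosl2 and Egr2 were nearly level at -0.07 and -0.05.

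Of 20 measured oncofetal and liver tumour markers, 9 were higher by 2-fold and none was lower by 2-fold. Their median was 0.71 against a random range of -0.05 to 0.25. After quantile or loess normalization 6 of the 20 were higher by 2-fold, and 10 were with the arrays centred. Igf2, a fetal growth factor, was 4.31-fold higher. Afp and Gpc3, named here after their values were seen, differed by 1.63 and 1.69. Tff3 and Igf2bp1 had the lowest values of this list, -0.52 and -0.35. The cell cycle list did not go with it: 0 of 23 members passed 2-fold in either direction, and its median of 0.05 lay at percentile 30.1. Rrm2 and Bub1 were at 0.45 and 0.41, and Birc5 and Bub1b at -0.52 and -0.42.

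**Figure D2:**
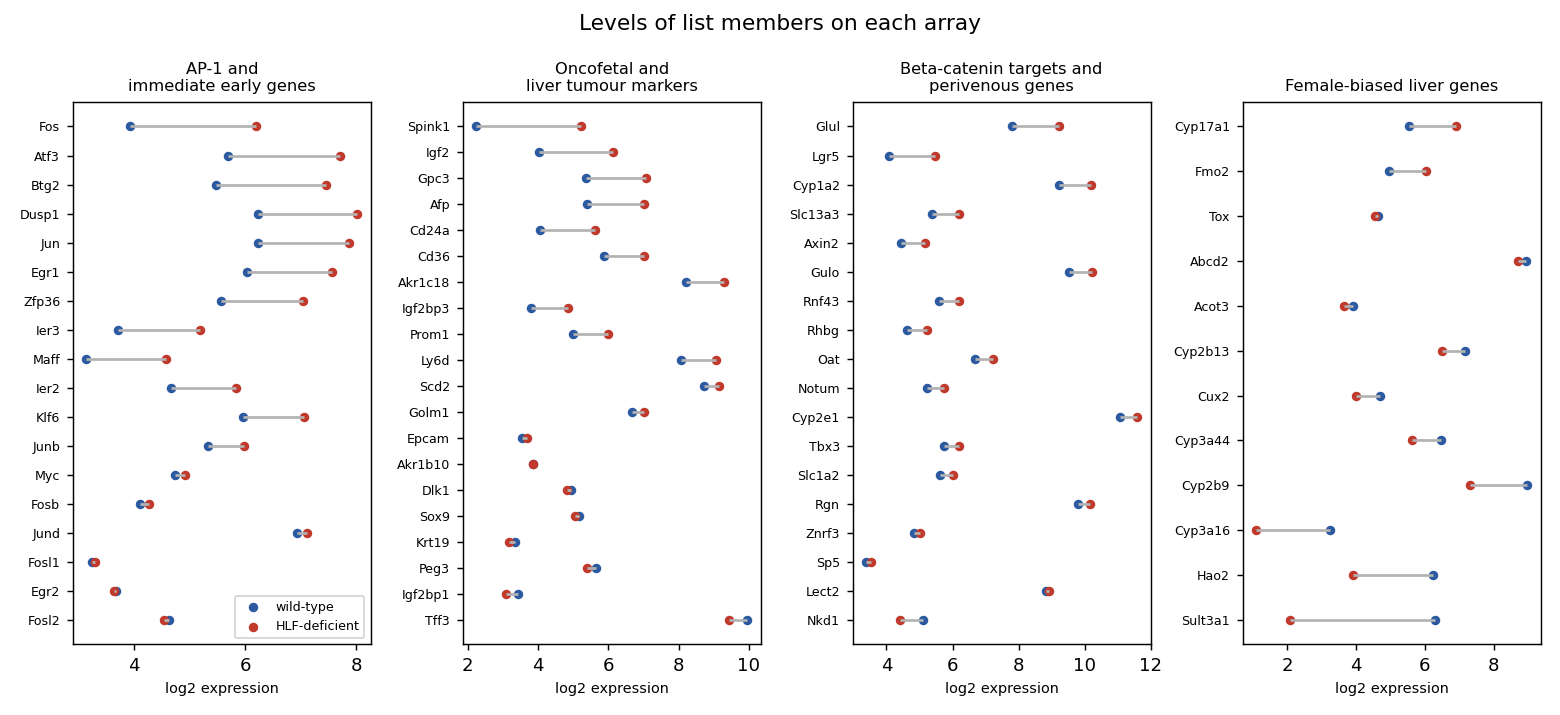
Log2 expression of each list member in the wild-type (blue) and HLF-deficient (red) tumour, 1 array each, for 4 lists, ordered by difference. With the values as deposited, red points lie to the right for 16 of 18 immediate early genes and 17 of 18 beta-catenin and perivenous genes, and to the left for 10 of 12 female-biased genes.

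Genes of the perivenous zone and targets of beta-catenin were higher as a group, with a median of 0.52 against a random range of -0.00 to 0.28. Of 18 members, 2 were higher by 2-fold, Glul, the glutamine synthetase of perivenous hepatocytes, at 2.68-fold, and Lgr5, a receptor for R-spondins, at 2.63-fold. A second probe set of Glul differed by 1.46. Nkd1 was the only member with a negative value, -0.70, with the values as deposited. Periportal genes had a median of -0.14 against a random range of -0.03 to 0.30, with Arg1 and Gldc at -0.43 and -0.35 and Pck1 at 0.94. The periportal median was -0.02 with the arrays centred and -0.25 after quantile or loess normalization, below its random range each time. As deposited, 0 of the 11 periportal members passed 2-fold, and Pck1 did at 1.06 with the arrays centred. The list lay inside the range with the mean in place of the median (-0.00081, percentile 6.03) and with unmatched random lists (percentile 5.58).

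The acute phase list had a median of 0.30 (random range 0.01 to 0.26) and a mean of 0.72, and 4 of 20 members passed 2-fold upwards. These were Saa3, Saa1 at 4.74-fold, Saa2 at 4.40-fold and Orm2 at 3.91-fold, so mostly genes of the Saa family, which are similar in sequence. Hp, Hpx and Fgb were nearly level at 0.11, 0.08 and 0.07, and Apcs and Il6ra differed by -0.12 and -0.07. Saa2, Orm2, Hp, Hpx and Fgb were named after their values were seen. Il6 itself was below the floor on both arrays. The matrix and stellate activation list had a median of 0.49 (random range -0.04 to 0.26). Of its 21 members, 3 were higher by 2-fold, among them Vim, an intermediate filament gene of mesenchymal cells, at 4.13-fold, and Sparc, a matrix glycoprotein, at 2.40-fold, while Tagln was at -0.01. The separate list of stellate cell and fibroblast markers lay on the lower boundary, with a median of -0.14 at percentile 2.5, and at percentile 2.34 when each array was centred. It lay well inside at percentile 25.5 after quantile normalization, 20.9 after loess and 13.3 with list means.

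Glycolysis and hypoxia genes had a median of 0.43 (random range -0.04 to 0.27), with Adm and Egln3, both hypoxia-induced, higher by 2.28-fold and 2.13-fold and Hk2 at -0.20. The median was 0.29 after loess normalization, still above its range. Car9 was at least 1.19-fold lower, its HLF-deficient value being below the floor. The list of p53 target and DNA damage genes had a median of 0.66 (random range -0.09 to 0.33), or 0.49 with genes below the floor set to it. Of its 17 genes, 13 entered the comparison, without Trp53, Cdkn1a, Bax and Gdf15. As deposited 3 were higher by 2-fold, and after quantile or loess normalization 1 was. Plk2 was 2.88-fold and Gadd45b 2.12-fold higher, and Bbc3 was at -0.21. Gadd45b was just under 2-fold, at 0.99, under quantile and loess normalization. Interferon response genes had a median of 0.34 (random range -0.07 to 0.28) although 0 of 17 passed 2-fold. Usp18 and Psmb9 had the largest values, 0.91 and 0.77, with Usp18 at 1.03 when the arrays were centred, and Ifit3 and Ifit2 the lowest, -0.21 and -0.07.

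**Figure D3:**
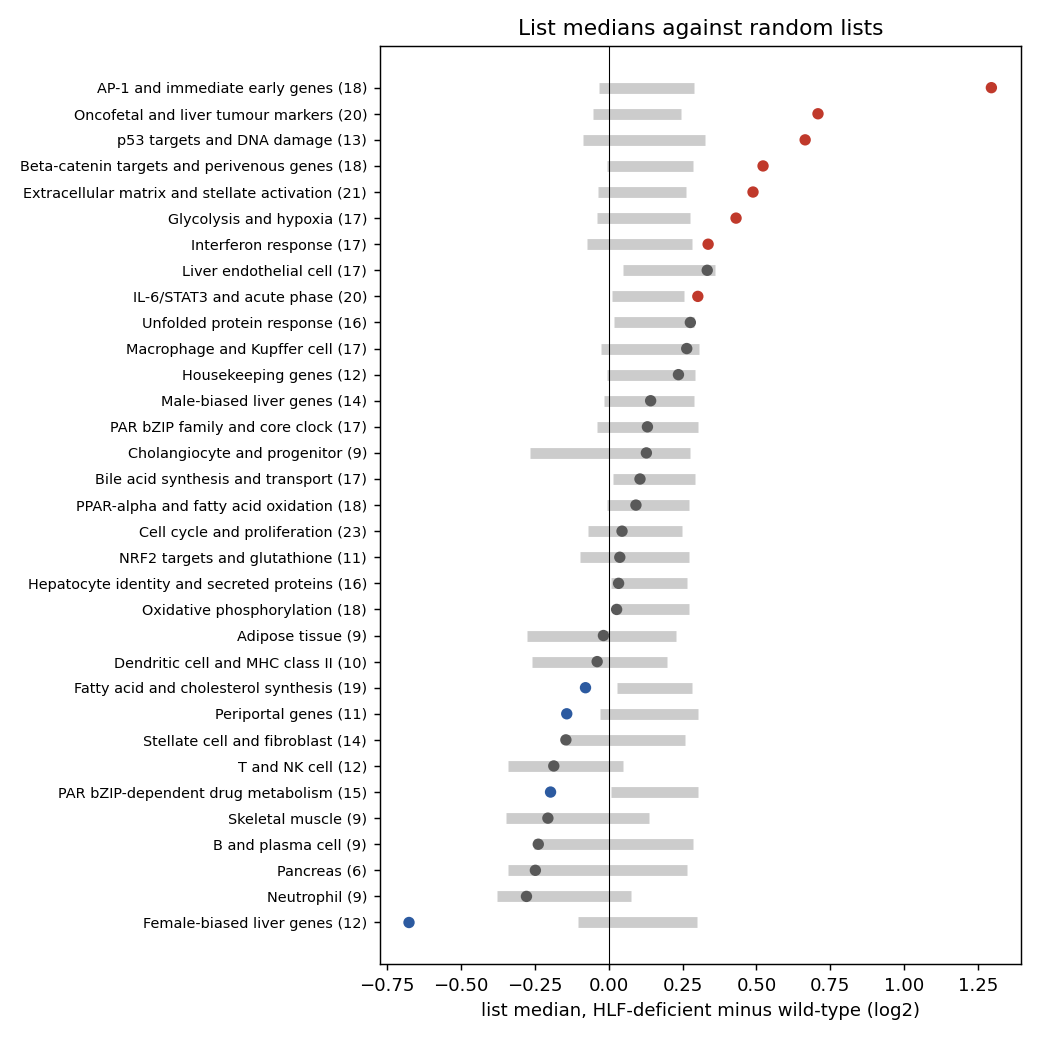
Median log2 difference (HLF-deficient minus wild-type) of each list with its number of members, against the central 95% of 10000 random lists matched on expression (grey bars). The 8 lists above the bars are red, the 4 below are blue and the 21 counted as inside are dark grey, with the stellate cell and fibroblast list on the lower end of its bar.

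Female-biased liver genes had the lowest median of all lists, -0.68 against a random range of -0.10 to 0.30, or -0.48 with genes below the floor set to it. Of 12 members, Sult3a1, Hao2 and Cyp2b9 were lower by 2-fold; Cyp3a16 was too in its measured value, but with that value below the floor only a bound of 1.23-fold holds. Higher by 2-fold were Cyp17a1, a steroid hydroxylase gene, at 2.53-fold and Fmo2 at 2.10-fold. Fmo2 was under 2-fold, at 0.94 and 0.95, after quantile and loess normalization. Male-biased genes lay inside the random range with a median of 0.14. Their largest increase was in Cyp7b1, an oxysterol hydroxylase, at 3.13-fold, followed by Cyp4a12a at 0.88 (just past 2-fold with the arrays centred), with Elovl3 and Mup3 at -0.58 and -0.51. The Y-linked gene Eif2s3y had levels of 6.52 and 6.49, and Xist was below the floor on both arrays at 1.64 and 1.68.

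Drug metabolism genes listed beforehand as dependent on PAR bZIP factors had a median of -0.20 against a random range of 0.01 to 0.30. Negative values were found for 13 of 15 members, or 10 of 15 with the arrays centred. The median was -0.07 with the arrays centred, -0.30 after quantile normalization and -0.31 after loess, and the mean of the members was -0.52; the list stayed below its random range in each case. The cytochrome genes Cyp2c54, Cyp2b9 and Cyp2c50 were the 3 members lower by 2-fold, and none was higher by 2-fold. The lowest values were mostly of the Cyp2c and Cyp2b families, with Cyp2b13 next at -0.67. Outside them Ugt2b1 was lowest at -0.34, and Alas1, Ces2a and Gsta3 were nearly level at -0.06, -0.04 and -0.04. These 5 genes were named after their values were seen. The list was not tested with 1 member per family. Ces3a and Ces1d had the largest values, 0.12 and 0.04. Without the 2 genes shared with the female-biased list the median was -0.19, still below the random range. Fatty acid and cholesterol synthesis genes had a median of -0.08 (random range 0.03 to 0.28), and 0 of 19 passed 2-fold. Elovl6 and Acacb were lowest at -0.61 and -0.37, and Me1 and Acaca highest at 0.38 and 0.30. The sign of this median turned to 0.04 when the arrays were centred, it was -0.26 after quantile normalization and -0.25 after loess, and the list lay inside the range of unmatched random lists at percentile 6.41.

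Other hepatocyte functions lay inside the random range, and the small medians of hepatocyte identity, bile acid, fatty acid oxidation, male-biased, cell cycle and oxidative phosphorylation genes turned to 0 or just below it after quantile or loess normalization. Hepatocyte identity genes had a median of 0.03 (percentile 6.03), with Alb at -0.15 and Foxa2 at 0.46. Bile acid genes had a median of 0.11 (percentile 28.8), with Cyp7b1 highest and Cyp8b1 lowest at -0.86, or -1.04 after quantile normalization. Fatty acid oxidation genes had a median of 0.09 (percentile 27.8), with Pdk4 and Fgf21 at 0.85 and 0.64 and Ehhadh at -0.43. Cyp4a10 lay just past 2-fold, with log2 levels of 5.07 and 4.07, and inside it at -0.99 after loess normalization and -0.88 with the arrays centred. NRF2 targets had a median of 0.04 (percentile 30.4), where Hmox1, a heme oxygenase, was 2.51-fold higher and Nqo1 was at -0.25. The unfolded protein response had a median of 0.28 (percentile 96.0) with Asns and Creld2 at 0.64 and 0.53. That median was 0.13 after quantile or loess normalization, and the list lay above the range with the mean of a gene's probe sets (percentile 97.51) and with unmatched random lists (percentile 98.4). Oxidative phosphorylation genes had a median of 0.03 (percentile 3.11). All 12 measured housekeeping genes had positive values as deposited, and 8 of 12 after quantile or loess normalization, with a median of 0.24 (percentile 89.8).

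With the values as deposited, 0 of the 11 cell type lists with a percentile passed the boundary, on which the stellate cell and fibroblast list lay at percentile 2.5. Under at least 1 alternative setting, endothelial or macrophage markers lay above the range and stellate, B cell, neutrophil, T cell, pancreas or muscle markers below it. Macrophage markers had a median of 0.26 (percentile 91.6), in which Cd14, an endotoxin co-receptor, was 3.62-fold higher and Gpnmb was at least 1.65-fold higher, while the Kupffer cell genes Clec4f and Vsig4 were at -0.37 and -0.36. Endothelial markers had a median of 0.33 (percentile 94.8) and lay above the range after quantile or loess normalization, with Lyve1 2.31-fold higher, Emcn at 0.98 (1.10 with the arrays centred), and the sinusoidal genes Clec4g and Fcgr2b at -0.76 and -0.45. T and NK cell markers had a median of -0.19 (percentile 35.9), B and plasma cell markers one of -0.24 (percentile 3.10) and neutrophil markers one of -0.28 (percentile 16.0). After quantile normalization these medians were -0.05, -0.25 and -0.13, and with the arrays centred -0.08, -0.12 and -0.16. Dendritic cell markers (-0.04, percentile 51.9), cholangiocyte markers (0.13, percentile 84.5), adipose markers (-0.02, percentile 51.5), pancreas markers (-0.25, percentile 10.4) and muscle markers (-0.21, percentile 20.7) were also inside. The dendritic and adipose medians were above 0 under each of the other scalings. After quantile normalization the macrophage, endothelial, cholangiocyte, muscle and stellate medians were 0.13, 0.21, 0.06, -0.07 and -0.04. In the adipose list Fabp4, which endothelial cells and macrophages also express, was 3.89-fold higher. The erythroid list, with 4 members above the floor, had a median of 0.33 and no percentile, and the sex chromosome list, also with 4, had one of 0.03.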

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

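The tests of explanations in this part were all chosen only after the results had been seen. Probe sets outside the gene comparison also differed between the 2 tumours, in both directions. Among 984 probe sets above the floor that name several genes, 16 were higher by 2-fold in the HLF-deficient tumour and 4 were lower. Among 5949 that name no gene, 141 were higher and 275 were lower, with a median difference of -0.10. The shares higher were 1.63% and 2.37%, against 1.49% of the 14649 genes compared. Probe sets that name no gene were thus more often lower than higher, whereas 219 of the genes compared were higher and 53 lower. The excess of increases therefore holds for probe sets that name genes and not for the whole array.

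The AP-1 and immediate early genes were higher in the HLF-deficient tumour, with a median of 1.30. A scaling shift between the arrays does not account for it. The median was 1.18 after quantile and 1.19 after loess normalization, above its random range each time. With the arrays centred it was 1.42, but centring moves the list and its random lists alike and so decides nothing here. Stress of the tissue before or during sampling is open and may have contributed: a list of 19 heat shock genes, written after Hspa1a and Hspb1 had been seen among the largest increases, had a median of 0.52 over 16 measured members against a random range of 0.03 to 0.31. Without these 2 genes the median was 0.41 over 14 members, at percentile 99.9. HLF deficiency and a difference between individual tumours also stay open, and with 1 array per genotype they cannot be told apart.

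The female-biased genes were lower, with a median of -0.68. Tumours from mice of different sex do not account for it, since the Y-linked genes Eif2s3y, Kdm5d and Uty were above the floor on both arrays with a median difference of 0.10, or 0.03 with Sry (-0.53) included, and Xist was below it on both. Counting several members of 1 gene family does not account for the whole shift either. With 1 member per family, the one that differed least, the median of 10 genes was -0.47 against a random range of -0.10 to 0.33. The probe set of a kept member may still read its relatives, so this cannot exclude an effect of shared sequence. HLF deficiency stays open beside differences between single tumours, and with 1 array per genotype they cannot be told apart.

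Ddx1 and Nbas, neighbours in the gene order of assembly GRCm38.p6, were lower together at -2.02 and -1.60, though 1 of the 3 probe sets of Nbas differed by -0.12 and their mean by -1.08. Across all expressed genes, 2 neighbouring pairs whose symbols differ in their first 3 letters were both lower by 2-fold, the other being Sult3a1 and Rsph4a. Leaving out Ddx1 and Nbas, which prompted the count, 1 such pair remains, and 16.1% of 10000 shuffles of the differences gave as many. That count rests on the other pair alone, so it cannot decide whether Ddx1 and Nbas were both lower by chance. Chance neighbours therefore stay open. A copy number change of this segment in either tumour could also produce such a pair and stays open. Cyria, 2 expressed genes away, had levels of 5.52 and 4.52 and differed by -0.88 with the arrays centred, but Mycn between them differed by -0.015, and a gene at a low level need not follow its copy number.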

How the results depend on the processing

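No paired analysis was possible because each genotype has 1 array, and no replicate could be left out. Hlf stayed lower by more than 2-fold under the 4 alternatives run for it, with differences between -1.34 and -1.22. Hlf has 1 probe set, so the mean of probe sets could not change its value. The rule of size set the counts by construction: 930 genes were higher and 458 lower at 1.5-fold, and 27 and 9 at 4-fold. Centring each array, which adds 0.12 to every difference, left 32 lower genes, all among the 53, and gave 294 higher genes that included all 219, so that 90.2% of the genes beyond 2-fold were higher in place of 80.5%. The other alternatives gave 189 to 219 higher and 37 to 57 lower genes; quantile normalization shared 169 higher and 40 lower genes with the values as deposited. All 8 lists above the random range stayed above it under the 8 alternatives run for lists. Of the 4 below, the female-biased and PAR bZIP-dependent lists stayed below under all 8. The fatty acid and cholesterol synthesis median changed sign, to 0.043, when the arrays were centred, by the shift centring adds, and stayed below its random range. That list and the periportal list lay inside the range of unmatched random lists, and the periportal list also with list means; the cause was not tested. Of the 33 list medians, 22 moved by more than the spread of random list medians under quantile and 23 under loess normalization; centring shifts lists and random lists alike, and unmatched random lists leave the medians as they are. Of 676 values of named genes under 4 alternatives, 25 changed sign, all of genes that differed by at most 0.13, 2 moved by more than the spread between probe sets (Macrod2 to -0.52 and Nbas to -1.08, both with the mean of a gene's probe sets, which for Macrod2 takes in 3 probe sets not above the floor and is -1.07 without them), and 21 crossed 2-fold. Many of these values could not move: centring adds 0.12, less than the spread of 0.24 between probe sets. The mean of probe sets leaves every gene with 1 probe set unchanged. Signal over background limits dim genes: values below the floor of 2.96 give only bounds.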

Other observations

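The genes and the test in this part were chosen after their values were seen, apart from Casp4, Ces1d, Ces3a, Clec4g, Fcgr2b, Hamp2 and Igf2. The inflammatory caspase genes Casp1, Casp4 and Casp12, which are neighbours in the gene order of assembly GRCm38.p6, were all higher in the HLF-deficient tumour, by 4.45-fold, 5.29-fold and 3.43-fold. The macrophage metalloelastase Mmp12 was 3.89-fold, the phagocyte oxidase gene Cybb 4.61-fold and Cd68 2.88-fold higher. Esm1 was 3.42-fold, the chemokine receptor Cxcr4 4.12-fold, Cd34 2.99-fold and Flt4 2.96-fold higher. These single genes were picked by their values. The fixed list of macrophage markers lay inside its random range as deposited (median 0.26, percentile 91.6) and after quantile normalization (percentile 88.1). It lay above the range with list means (percentile 99.9) and with unmatched random lists (percentile 97.7). The fixed list of endothelial markers lay inside its random range as deposited (median 0.33, percentile 94.8) and above it after quantile normalization (percentile 98.6), loess normalization (percentile 98.8) and with unmatched random lists (percentile 99.55). The sinusoidal endothelial genes Clec4g, Fcgr2b and Dnase1l3 were at -0.76, -0.45 and -0.32, and Stab2 was at -0.06.

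Hamp, the gene of hepcidin, the liver hormone that limits iron export, was 2.62-fold lower. The hepcidin-type gene Hamp2 was 4.59-fold lower. Whether a probe set of 1 of these related genes also reads the other was not tested. The carboxylesterases Ces1g and Ces1e were lower by 2.98-fold and 2.85-fold. The carboxylesterases of the fixed drug metabolism list, Ces1d, Ces3a and Ces2a, were nearly level at 0.04, 0.12 and -0.04. The insulin-like growth factor binding protein genes Igfbp3 and Igfbp1 were higher by 4.81-fold and 3.35-fold, in the same direction as Igf2. Neighbouring pairs of genes that differ in the first 3 letters of their symbols and were both higher by 2-fold numbered 4, against 3.08 on average in shuffled differences, and 36.9% of shuffles gave as many.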
